A study of Mus musculus with 383 samples.

How the data were processed

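Single nuclei were collected from the vagal dorsal motor nucleus, the brainstem nucleus that holds the preganglionic motor neurons of the vagus nerve. Per the labels' protocols, male Chat-IRES-Cre mice, in which Cre recombinase is made in cholinergic cells, received 100 nL of a Cre-dependent virus that tags nuclei with the red protein mCherry. They were injected at 10 weeks of age, and tissue was taken 16 days later. The protocol speaks of sections around the suprachiasmatic nucleus, a hypothalamic nucleus, although the tissue is named as the vagal motor nucleus, and this was not resolved. Tissue was pooled, and nuclei positive for mCherry and for a DNA dye were sorted 1 per well into 96-well plates. Libraries were made with the Smart-seq2 protocol, which copies transcripts along their length, with 22 cycles of cDNA amplification and no molecular identifiers.

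The deposited table holds read counts for 29779 genes in 383 nuclei, not normalised, with symbols as gene names. Per the submitters' processing notes, the genome build was GRCm38, and the tools named were bcl2fastq, STAR, Picard, edgeR and Seurat version 3. The notes as used here give these names without roles. The gene annotation, the counting mode and the use of strand were not given in the sources used here. All columns matched 1 nucleus each, and all values were whole numbers.

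Each library is 1 nucleus, and the labels name no animal. The whole series therefore counts as 1 sample, and nuclei do not stand for replicate animals. Intervals, the rule that intervals must not overlap and ranges over resampled nuclei take the nucleus as the unit. They do not cover variation between animals. No hypothesis test between nuclei or clusters was run, and no p-value, standard error or count of significant genes was computed. To weigh explanations of patterns, gene lists were ranked among random lists of genes matched on share, and genes or nuclei were resampled. Shares of nuclei are given with exact Clopper-Pearson 95% intervals, and summed reads, scaled by all reads of the class or cluster (RPM), were computed with exact Poisson 95% intervals. Both cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Where a gene was found in 0 nuclei of a class or cluster, the upper limit of its interval is given once for each number of nuclei. For nuclei left out by the filter, a floor of 3 nuclei was used. A gene counted as detected in a nucleus with at least 1 read.

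Nuclei were retained with at least 1000 detected genes and at most 10% of reads on mitochondrial genes. Counts were scaled to 10000 per nucleus and log-transformed after adding 1. The 2000 most variable genes gave 15 principal components, a graph of 10 nearest neighbours and Leiden clusters at resolution 1. A first clustering assigned retained nuclei to classes from cell type markers fixed before the data were examined. A cluster was called motor-like where the mean share over 6 cholinergic markers exceeded that of each list for another cell type. It was then called visceral or somatic by the larger of the mean shares over 5 visceral and 6 somatic motor markers. The markers also covered all neurons, glutamatergic, inhibitory, catecholaminergic and serotonergic neurons, oligodendrocytes and their precursors, astrocytes, microglia, vascular cells and ependymal cells. One nucleus was sorted per well, and no doublet caller was run.

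Visceral motor-like nuclei were clustered a second time without mitochondrial genes, ribosomal protein genes or any listed gene, so that the listed genes took no part in building the clusters they were compared across. These held-out lists covered neuropeptides, gut and metabolic peptide receptors, opioid and cannabinoid receptors, monoamine and acetylcholine receptors, GABA, glycine and glutamate receptors, ion channels, transcription factors, nitric oxide and calcium-binding proteins, immediate early genes, axon injury genes and interferon response genes. Of their 438 genes, 434 were in the table. The list of monoamine and acetylcholine receptors also held receptors for adenosine and ATP, among them Adora1 and P2rx2. Because nuclei differed in depth, each was thinned to 500000 reads before shares were compared between clusters or classes. This was the largest preset number that at least 90% of visceral motor-like nuclei reached, and it left out 21 of them and none of the somatic motor-like nuclei. The comparison of classes used a separate random draw from that used for the clusters, so a gene's share over all visceral motor-like nuclei differs slightly between them. Clusters of at least 8 nuclei were compared.

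Genes were named by rules fixed before the data were examined. Chat, Slc18a3, Slc5a7, Cck, Pdyn, Grp and Nos1 were always named. Held-out genes were named where the thinned share differed by at least 40 percentage points between the highest and the lowest cluster with intervals that did not overlap, up to the 30 largest. Between the clusters with the highest Cck, Pdyn and Grp shares, up to 10 genes each way were named at 40 points. The 3 most often detected genes of each list were named, and the 5 leading genes of a cluster among those used to build it served only to describe it. The same limit of 40 points with intervals apart was applied between the visceral and somatic classes, and between a cluster and all others. Genes named outside these rules were chosen after their values were seen. These are the markers Slc1a3, Tph2, Ddc, Slc18a2, Mbp, Dnah12 and Pecam1 and those so marked in the text. The comparisons between classes and of a cluster with all others were added after the clusters had been seen. Values of some genes that these rules selected are not reported here.

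Alternatives covered the minimum of detected genes, the mitochondrial limit, each clustering setting, pooled size factors, a stricter detection limit, unthinned reads and consecutive blocks of 96 nucleus numbers. The labels do not say which nuclei shared a plate, so these blocks are only a stand-in for one. The stability of clusters was measured by splitting the variable genes at random into 2 sets 20 times, clustering from each, and taking the adjusted Rand index, which is 1 for identical clusters and near 0 for unrelated ones.

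The procedure for listed genes across clusters was tested on simulated data made by shuffling 25295 genes over the 316 retained nuclei, with 3 planted groups. Planted genes were given to 90% of nuclei of their group and 20% of others. Each planted group was larger than any visceral motor cluster reported below. Genes were shuffled separately, which removed differences in quality shared between genes, apart from depth. The rates below therefore need not hold for the real clusters. With 1000 planted genes available to the clustering, 93.4% of nuclei fell in clusters of their own group, and 194 of 200 further planted genes were recovered. With 500 such genes 76 of 200 were recovered, and with 100 none was. Of 409 shuffled listed genes, 0, 3 and 0 passed the limit of 40 points in these runs with 1000, 500 and 100 genes. Shuffled data with no planted genes still gave 8 clusters, with 2 of 409 genes past the limit, so the number of clusters is by itself no evidence of cell types. The planting was widened to 500 and 1000 genes after a first version with 100 genes had recovered few of them.

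Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with scran 1.30.0. Gene positions were taken from the GENCODE vM21 annotation of GRCm38, in which 28340 of the 29779 symbols (95.2%) were found. Of 104 named genes, 15 share exon sequence with another gene of the table, and among these only Hoxd3 does so on its own strand, with Hoxd4 and Gm28230. Reads of such pairs could not be told apart without knowledge of the counting.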

Results

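The series profiled single nuclei from the vagal dorsal motor nucleus of male mice, tagged through Cre activity at the choline acetyltransferase locus, and its title names the selectivity of vagal output to the gut through genetically defined neurons. Read counts of 383 nuclei were analysed here. The nuclei formed a single group without replicate animals, so the comparisons below are between classes and clusters of nuclei found within it. Reads per nucleus ranged from 159 to 4699420, with a median of 1293019, and the median nucleus had 10841 genes detected. The filter retained 316 nuclei (82.5%). The retained nuclei had a median of 1440075 reads and 11234.5 genes, and a median of 0.0868% of reads on mitochondrial genes. The 67 nuclei not retained had a median of 2328 reads and 344 genes.

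**Figure D1:**
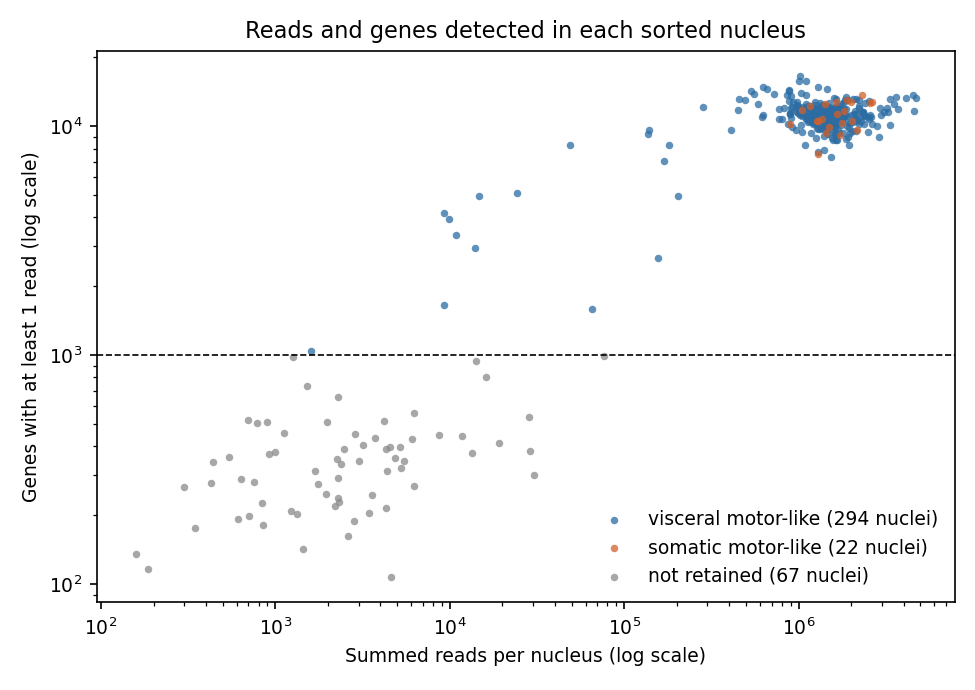
Each point is 1 nucleus, with its summed reads on a log x axis and its number of genes with at least 1 read on a log y axis, coloured by class; the dashed line is the minimum of 1000 genes. The 67 nuclei below the line reach at most 76739 reads, whereas the retained nuclei have a median of 1440075.

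The first question was whether the sorted nuclei were cholinergic motor neurons. Nearly all retained nuclei carried the cholinergic genes, and the median shares of marker lists for other cell types were lower, although single markers of them were frequent. Chat, which encodes the acetylcholine-synthesising enzyme, was detected in 304 of 316 nuclei (96.2%, 95% interval 93.5 to 98.0). Slc18a3, the vesicular acetylcholine transporter, was detected in 94.0% (90.8 to 96.3), and Slc5a7, the high-affinity choline transporter, in 95.6% (92.7 to 97.6). All 3 genes were found in 286 nuclei (90.5%, 86.7 to 93.5) and none of them in 3 nuclei. Tbx20, a transcription factor of visceral motor neurons, was detected in 88.9% (84.9 to 92.2). Nos1, which encodes neuronal nitric oxide synthase, was detected in 92.7% (89.3 to 95.3). Slc18a3 lies inside Chat on the same strand of chromosome 14 (32462438 to 32464850 within 32408203 to 32465989, GRCm38) without sharing an exon, so intronic reads of the pair may not be separable.

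The median share over a marker list was 98.7% for neurons, 94.8% for cholinergic neurons and 56.3% for visceral motor neurons. It was 6.96% for somatic motor neurons, 18.0% for glutamatergic, 23.6% for inhibitory, 31.3% for catecholaminergic and 21.5% for serotonergic neurons. For glia and other cells it was 13.9% for oligodendrocytes, 9.81% for oligodendrocyte precursors, 20.3% for astrocytes, 10.6% for microglia, 7.59% for vascular cells and 7.91% for ependymal cells. Some single markers were frequent within these lists, and those given here are not all. Ddc and Slc18a2, which act in monoamine synthesis and storage, were detected in 89.2% and 86.4% of nuclei, Mbp of oligodendrocytes in 76.9%, Dnah12 of ependymal cells in 69.9% and Pecam1 of vascular cells in 67.7%.

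The first clustering gave 9 clusters, of which 8 were visceral motor-like and 1 was somatic motor-like. The visceral motor-like class held 294 nuclei (93.0% of those retained) and the somatic motor-like class 22 (6.96%). The same 294 and 22 nuclei were obtained when the listed genes were left out of the clustering, an alternative chosen after seeing the data. Median depth was 1431008 reads in the visceral and 1646060 in the somatic motor-like class.

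Between the somatic and visceral motor-like nuclei, some ion channel, receptor and peptide genes differed widely, while most genes of these lists did not pass the limit. At 500000 reads, Kcna1, a voltage-gated potassium channel, was detected in 22 of 22 somatic motor-like nuclei (100%, 84.6 to 100) and in 17.6% (13.3 to 22.6) of 273 visceral motor-like nuclei. Scn4b, a sodium channel subunit, was detected in 86.4% (65.1 to 97.1) and 12.8% (9.10 to 17.4). The receptors Htr7 for serotonin, Adora1 for adenosine and Tacr1 for substance P were detected in 95.5%, 90.9% and 90.9% of somatic motor-like nuclei, against 30.4%, 30.8% and 37.4%. Calcb and Calca, which encode calcitonin gene-related peptides, were detected in 63.6% and 59.1% against 5.50% and 4.03%. Both are close paralogs, so their reads may be split uncertainly. Vipr2, Trhr, Kcnk9, Lhx4 and Meis2 were also higher by at least 40 points.

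In the other direction, Adcyap1, which encodes the peptide PACAP, was detected in 1 of 22 somatic motor-like nuclei (4.55%, 0.115 to 22.8) and in 92.3% (88.5 to 95.2) of visceral motor-like nuclei. Its summed reads were 0.0909 and 190.1 RPM. Gal, which encodes galanin, was detected in 22.7% (7.82 to 45.4) against 94.9% (91.6 to 97.2). The nuclear receptor gene Nr4a2 was detected in 0 of 22 nuclei, with an upper 95% limit of 15.4%, against 86.4%. The nicotinic receptor subunit gene Chrna3 was detected in 13.6% against 83.5%, Chrna5 in 0 of 22 against 56.0% and Chrnb4 in 13.6% against 59.3%. The other listed nicotinic subunits did not pass the limit. Npy2r, a receptor for neuropeptide Y and peptide YY, was detected in 4.55% against 58.6%, P2rx2, an ATP-gated channel, in 0 of 22 against 52.8%, and Nos1 in 40.9% (20.7 to 63.6) against 93.4% (89.8 to 96.0). Scn3b, Hcrtr1, Cnr1, Adra2a, Hpcal4, Hoxd3 and Nkx6-1 were lower as well.

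By list, 12 held-out genes were higher and 19 lower in the somatic motor-like class. Of 51 neuropeptide genes 2 were higher and 2 lower, of 54 peptide receptors 3 higher and 2 lower, and of 47 monoamine and acetylcholine receptors 2 higher and 5 lower. The last list also held receptors for adenosine and ATP, with Adora1 among its higher and P2rx2 among its lower genes. Of 87 ion channels 3 were higher and 1 lower, and of 91 transcription factors 2 higher and 6 lower. Of 16 nitric oxide and calcium-binding genes 2 were lower, of 5 opioid and cannabinoid receptors 1 was lower, and of 11 axon injury genes the 2 lower ones were Adcyap1 and Gal. None of 44 GABA, glycine and glutamate receptors, 17 immediate early genes or 14 interferon response genes passed the limit. In each of the 4 blocks of nucleus numbers, which held 3 to 7 somatic motor-like nuclei, all 12 and 19 genes kept their direction. These genes were chosen over the same nuclei, so the blocks give no independent support. Tbx20 (27.3% against 93.8%), Tbx3, Lhx4, Chodl and Calca were among the markers that named the classes and are no independent evidence. With at least 5 reads required, 19 genes were higher, 10 of them among the 12.

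**Figure D2:**
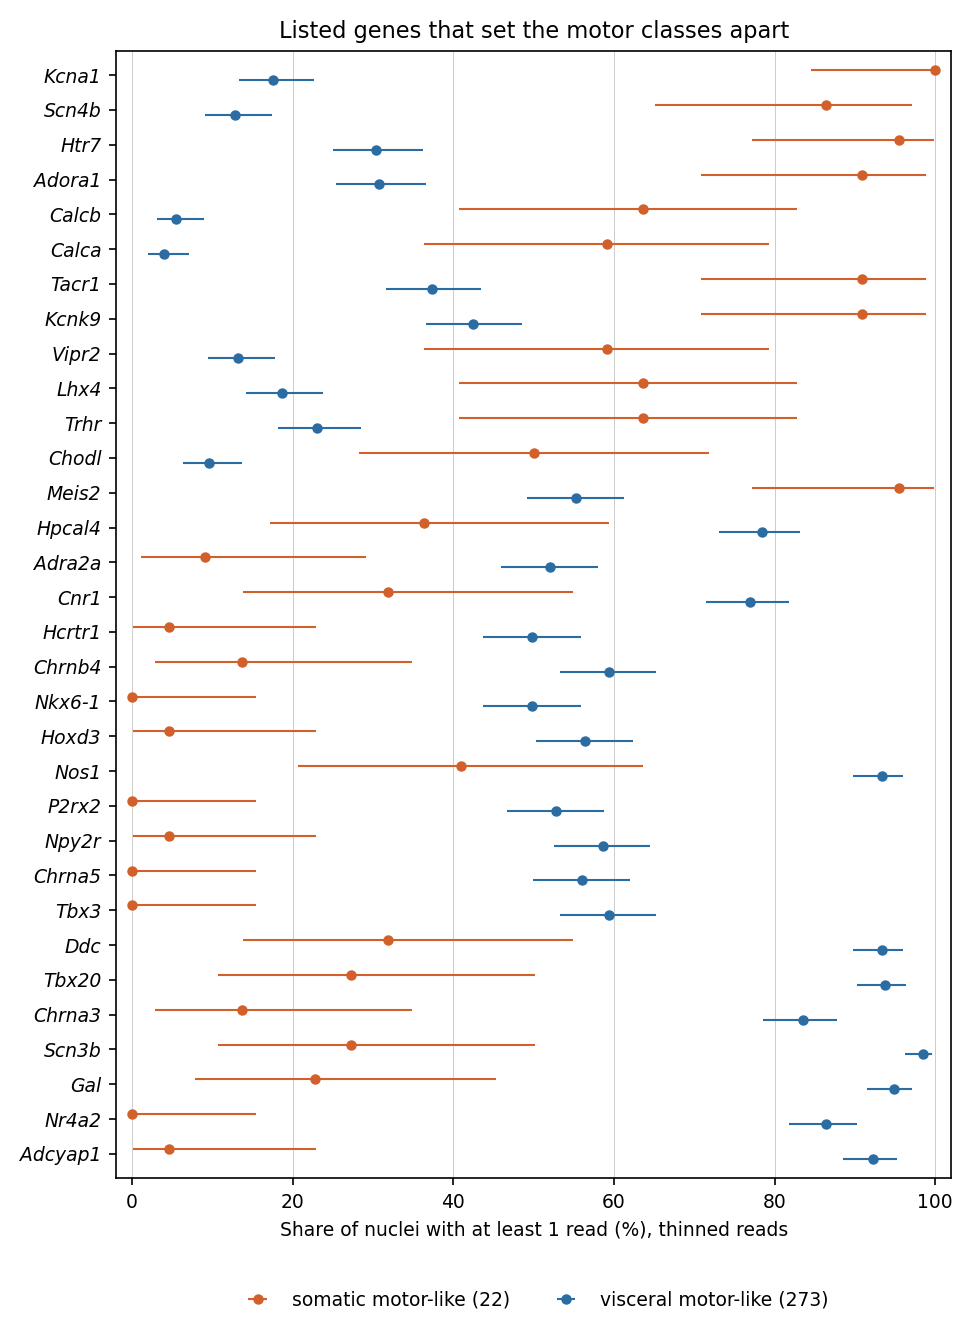
Points give the share of nuclei with at least 1 read after thinning to 500000 reads in 22 somatic motor-like nuclei (orange) and 273 visceral motor-like nuclei (blue), with exact 95% intervals, for reported genes that differed by at least 40 points with intervals apart. Kcna1 stands at 100% against 17.6% and Adcyap1 at 4.55% against 92.3%.

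Most listed ion channels (67 of 87) and GABA, glycine and glutamate receptors (37 of 44) were found in over 50% of visceral motor-like nuclei. This held for 7 of 54 peptide receptors, 17 of 47 monoamine and acetylcholine receptors and 9 of 51 neuropeptide genes. Among the most often detected genes of each list after thinning, Nxph1 was detected in 273 of 273 nuclei, and Chgb and Scg2, genes of dense-core vesicle proteins, in 98.5% each. Igf1r and Insr were detected in 99.3% each and Adcyap1r1, the PACAP receptor, in 95.2%. Oprl1, Cnr1 and Oprm1 were detected in 78.8%, 77.3% and 75.5%, and Chrnb2, Chrna3 and Chrm3 in 93.8%, 82.4% and 79.5%. Gabbr2, Gria1, Cacna1a, Cacna1b, Cacna1c, Rora and Gap43 were detected in every nucleus, and Meis1 and Gucy1a2 in 99.6% each. Hpcal1 and Ncald were detected in 99.3% and 98.5%, Ecel1 and Gal in 98.5% and 95.6%, and B2m, Ifi27 and Stat2 in 99.3%, 95.2% and 92.7%. Immediate early genes were less frequent, led by Jun (68.1%), Jund (63.0%) and Btg2 (38.5%).

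The second clustering, built without any listed gene, divided the 294 visceral motor-like nuclei into 9 clusters of 52, 49, 48, 35, 35, 22, 21, 18 and 14 nuclei, numbered by size. Of 434 held-out genes, 125 differed by at least 40 points between their highest and lowest cluster with intervals apart. These were 9 of 51 neuropeptide genes, 21 of 54 peptide receptors, 2 of 5 opioid and cannabinoid receptors, 17 of 47 monoamine and acetylcholine receptors and 8 of 44 GABA, glycine and glutamate receptors. They were also 18 of 87 ion channels, 33 of 91 transcription factors, 5 of 16 nitric oxide and calcium-binding genes, 4 of 17 immediate early genes, 3 of 11 axon injury genes and 6 of 14 interferon response genes. Cluster 6 was the lowest cluster of 40 of the 125 genes and the highest of 17, and cluster 1 was the highest of 45. Without cluster 1, whose nuclei also had reads of other cell types' markers more often, 90 genes passed, an alternative chosen after seeing the data. The count was 69 when nuclei with at least 500 genes were kept, 80 with 20 neighbours and 100 without thinning. With the genes split at random into 2 sets, the clusters had a median adjusted Rand index of 0.406 (0.292 to 0.497 over 20 splits), against -0.000399 after shuffling.

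**Figure D3:**
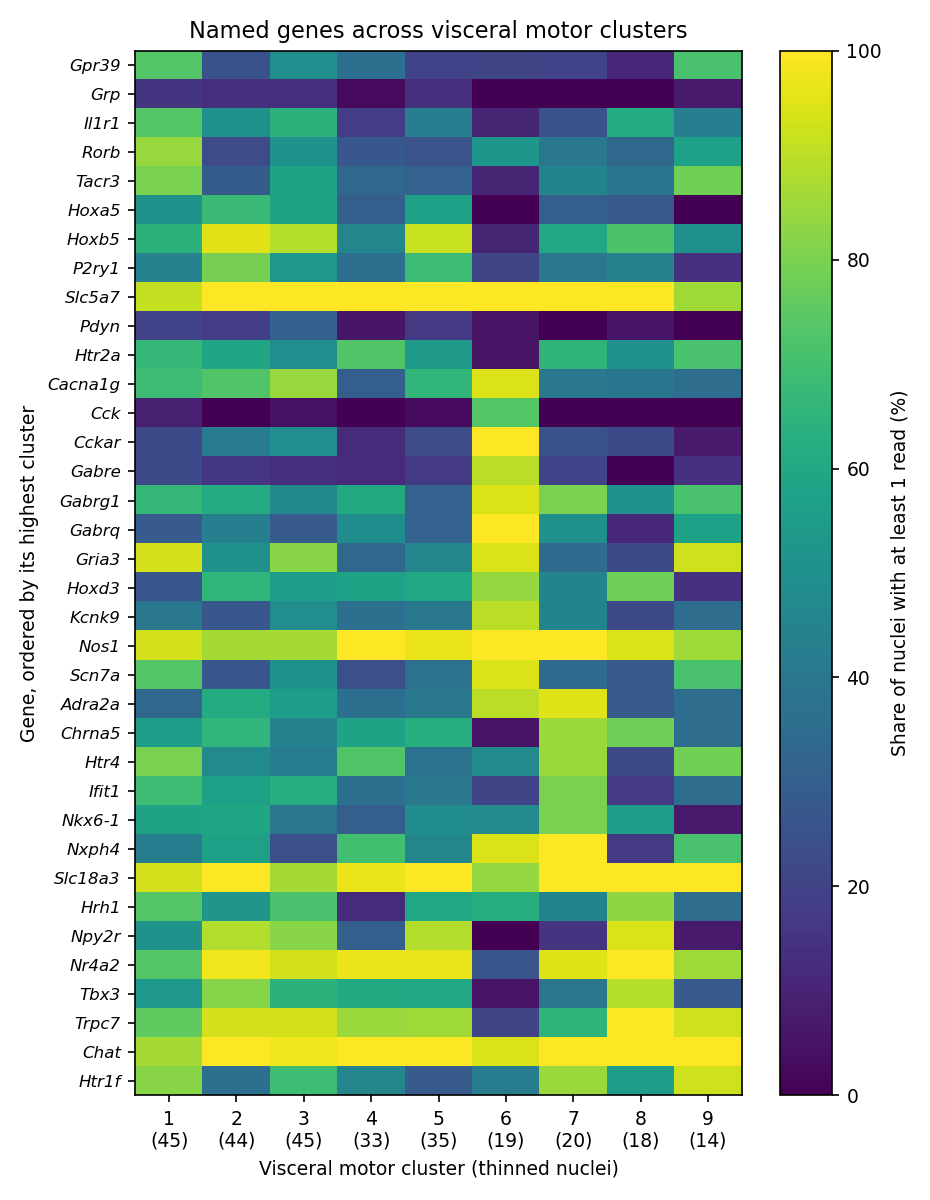
Colour gives the share of nuclei with at least 1 read after thinning to 500000 reads, from 0 to 100%, for each reported gene (rows) in each visceral motor cluster (columns, with the number of thinned nuclei). Cck stands at 73.7% in cluster 6 and at most 8.89% elsewhere, while Npy2r is at 0 of 19 nuclei in cluster 6 and 94.4% in cluster 8.

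Among the visceral motor clusters, the Cck cluster was the one most set apart by listed genes, although not all of these traits were particular to it. Cck, which encodes cholecystokinin (chromosome 9, 121489824 to 121495694, GRCm38), was detected in 14 of 19 thinned nuclei of cluster 6 (73.7%, 48.8 to 90.8) and in 7 of 254 other nuclei (2.76%, 1.12 to 5.6). Its summed reads were 94.2 and 0.575 RPM, and its unthinned share in cluster 6 was 72.7%. Cckar, the gene for the cholecystokinin A receptor (chromosome 5, 53697776 to 53707705), was detected in 19 of 19 nuclei (100%, 82.4 to 100) against 28.3% (22.9 to 34.3), with 260.3 and 26.0 RPM. The GABA-A receptor subunit genes Gabre and Gabrq were detected in 89.5% (66.9 to 98.7) and 100% (82.4 to 100) against 15.4% and 36.2%. The potassium channel gene Kcnk9, the sodium channel gene Scn7a, Nxph4 and the adrenergic receptor gene Adra2a were detected in 89.5%, 94.7%, 94.7% and 89.5% against 37.8%, 43.7%, 50.0% and 48.0%.

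By the same limit, 9 listed genes were lower in cluster 6. Npy2r was detected in 0 of 19 nuclei, with an upper 95% limit of 17.6%, against 63.4% (57.1 to 69.3). Hoxb5 and Hoxa5, transcription factors of the anterior-posterior axis, were detected in 10.5% (1.30 to 33.1) and 0 of 19 nuclei against 74.8% (69.0 to 80.0) and 47.2% (41.0 to 53.6). Nr4a2 was detected in 26.3% (9.15 to 51.2) against 91.7% (87.6 to 94.8), the cation channel gene Trpc7 in 21.1% against 86.2%, and Tbx3 in 5.26% against 62.2%. The serotonin receptor gene Htr2a, the nicotinic gene Chrna5 and the neurotensin receptor gene Ntsr1 were detected in 5.26%, 5.26% and 0 of 19 nuclei against 60.2%, 59.4% and 40.9%. In the 3 blocks of nucleus numbers with at least 3 thinned nuclei of cluster 6, all 51 comparisons of these 17 genes kept their direction. The genes were chosen for wide differences over these same nuclei, so this is no independent support. Some traits of cluster 6 were shared with the somatic motor-like class. Against the visceral motor-like class, Kcnk9 was also higher there, and Npy2r, Nr4a2, Chrna5 and Tbx3, a marker that named the classes, were also lower. Adra2a went the other way, and the remaining genes did not pass the limit between classes. Cck was among these, but it was detected more often in somatic than in visceral motor-like nuclei. Its intervals were apart, as given under Other observations, so the Cck trait was partly shared too. In the cluster matched to cluster 6, the Cck share was 35.9% at resolution 0.5, 32.6% with 20 neighbours and 14.3% when nuclei with at least 500 genes were kept.

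**Figure D4:**
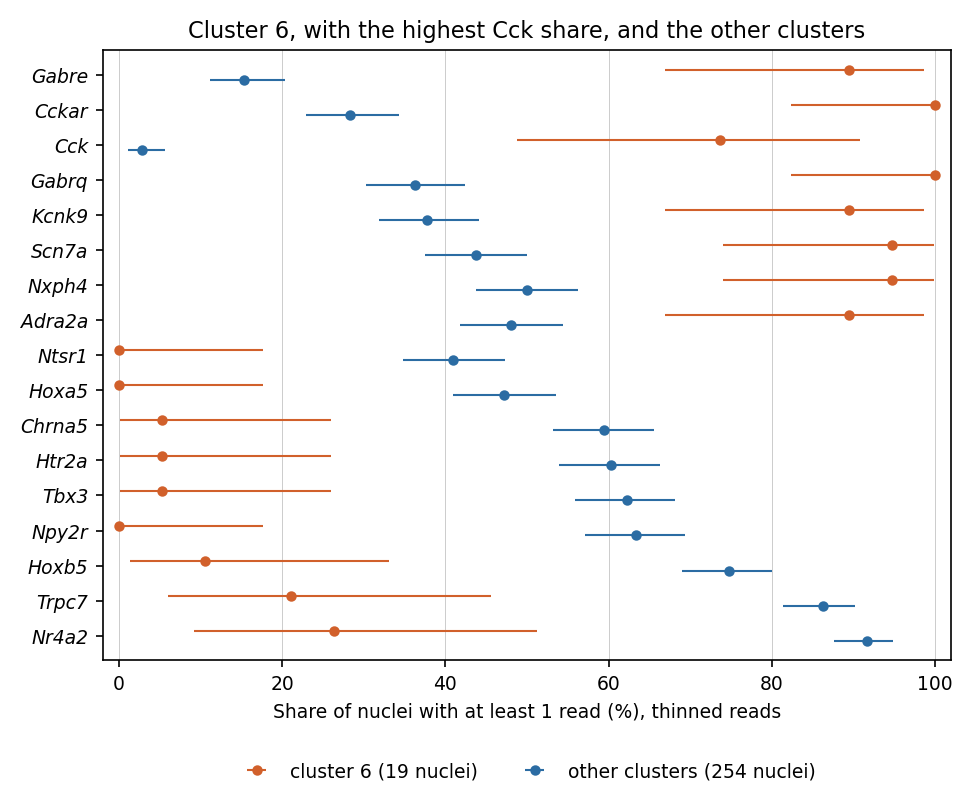
Points give the share of nuclei with at least 1 read after thinning, with exact 95% intervals, in 19 nuclei of cluster 6 (orange) and 254 nuclei of the other visceral motor clusters (blue), for listed genes that differed by at least 40 points with intervals apart. Cckar stands at 100% against 28.3% and Npy2r at 0% against 63.4%.

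Npy2r divided the other clusters too. It was detected in 94.4% (72.7 to 99.9) of cluster 8, 88.6% of clusters 2 and 5, 82.2% of cluster 3 and 51.1% of cluster 1. In cluster 4 it was found in 30.3% (15.6 to 48.7), in cluster 7 in 15.0% (3.21 to 37.9) and in cluster 9 in 7.14% (0.181 to 33.9). Cluster 7 had Nxph4 and Chrnb4 in 20 of 20 nuclei, against 49.4% and 57.7% of the other nuclei, and the interferon response gene Ifit1 was highest there (80.0%) and lowest in cluster 8 (16.7%). The median mitochondrial share was 0.159% in cluster 7 and 0.0201% in cluster 8, and ribosomal protein genes had a median log2 ratio of 0.80 for cluster 7 over cluster 4. The histamine receptor gene Hrh1 was lowest in cluster 4, at 12.1% against 62.5% of other nuclei, and the glutamate receptor gene Gria3 was lowest in cluster 8, at 22.2% against 65.1%. Without thinning, Gria3 was detected in 66.7% of cluster 8 and 95.5% of cluster 6, under 40 points apart, and it was lower in cluster 8 in only 2 of 3 blocks. Cluster 9 lacked detectable Hoxa5 (0 of 14, upper limit 23.2%) and had Hoxd3 and Nkx6-1 in 14.3% and 7.14% against 56.0% and 51.0%. Tbx3 was highest in cluster 8 (88.9%), where Tbx3os1, whose exons overlap those of Tbx3 on the other strand, was among the genes that built the cluster.

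Cluster 1 was the highest cluster of 45 of the 125 genes, and its nuclei also had the most genes detected at 500000 reads, a median of 11484 against 9416 to 10917.5 in the other clusters. The nuclear receptor gene Rorb was detected in 84.4% (70.5 to 93.5) of its 45 nuclei against 36.4% (30.1 to 43.0), Calcr, the calcitonin receptor gene, in 71.1% against 21.5%, and Gpr39, a zinc-sensing receptor gene, in 73.3% against 31.6%. Tacr3, Tshr and Npr3 were higher as well, and Atf3, a stress-induced transcription factor, was detected in 66.7% (51.0 to 80.0) against 12.7% (8.69 to 17.8). The same nuclei more often had reads of Slc1a3 of astrocytes (71.1% against 32.9%) and Tph2 of serotonergic neurons (62.2% against 24.1%). They had Chat in 86.7%, the lowest share among the clusters.

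Further genes among the 30 with the widest range were as follows. Il1r1, the interleukin 1 receptor gene, ranged from 10.5% in cluster 6 to 73.3% in cluster 1, and Htr1f from 28.6% in cluster 5 to 92.9% in cluster 9. Without thinning, Htr1f was detected in 65.7% of cluster 5 and 100% of cluster 9, under 40 points apart. Htr4 ranged from 22.2% in cluster 8 to 85.0% in cluster 7, but this order reversed (by -1.22 points) when nuclei with at least 500 genes were kept. Cacna1g ranged from 30.3% in cluster 4 to 94.7% in cluster 6. P2ry1 ranged from 14.3% in cluster 9 to 79.5% in cluster 2, and Gabrg1 from 31.4% in cluster 5 to 94.7% in cluster 6.

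In these clusters, Pdyn and Grp were each found in fewer than 50% of the nuclei of any cluster, which for Pdyn depended on the setting. Pdyn, which encodes prodynorphin (chromosome 2, 129686565 to 129699844), was highest in cluster 3, at 14 of 45 nuclei (31.1%, 18.2 to 46.6). It was also found in 20.0% of cluster 1, 18.2% of cluster 2 and 17.1% of cluster 5, and in 0 of 20 nuclei of cluster 7, with an upper limit of 16.8%. Its summed reads were 56.4 RPM in cluster 3 and 48.1 in cluster 2. Grp, which encodes gastrin-releasing peptide (chromosome 18, 65872820 to 65886596), was found in 15.6% (6.49 to 29.5) of cluster 1, 13.6% of cluster 2, 13.3% of cluster 3 and 14.3% of cluster 5. Its summed reads in RPM were higher in cluster 2 (16.2) than in cluster 1 (5.87), so no order was read among these. Under other clustering settings the highest Pdyn share of any cluster ran from 23.7% with nuclei of at least 500 genes to 60.5% with nuclei of at least 2000 genes. With pooled size factors it was 56%, in another cluster than the one matched to cluster 3 (8.70%).

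Between the Cck cluster and the cluster with the highest Pdyn share, 9 held-out genes were higher and 16 lower by at least 40 points. Chrm2, the muscarinic M2 receptor gene, was detected in 100% (82.4 to 100) of cluster 6 and 55.6% (40.0 to 70.4) of cluster 3. Crhr1, Kcnh8 and Il1r1 were detected in 15.8%, 31.6% and 10.5% of cluster 6 and in 68.9%, 82.2% and 64.4% of cluster 3. Cluster 1 was compared because its Grp share was the highest by value, but no order was read for Grp, so it does not stand for Grp nuclei. Against cluster 1, cluster 6 was higher for 9 genes, among them Hcrtr1 (78.9% against 20.0%), and lower for 35, among them Trpv1 (0 of 19 against 55.6%). Clusters 3 and 1 differed by 4 genes, Atf3, Nr4a3, Npr3 and Calcr, all higher in cluster 1. After thinning, cluster 1 also had the most genes detected (median 11484). Markers of other cell types were higher there in 45 of 50 cases. The genes higher in cluster 1 therefore cannot be told apart from wider detection in its nuclei.

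Of the genes chosen for co-detection, all but Nos1 were found in a minority of visceral motor-like nuclei, and a few pairs were found together more often than the product of their shares. Over all reads of 294 nuclei, Cck was detected in 27 (9.18%, 6.14 to 13.1), Pdyn in 43 (14.6%, 10.8 to 19.2) and Grp in 31 (10.5%, 7.28 to 14.6). Penk was detected in 49, Tac1 in 13, Vip in 27, Sst in 24 and Calca in 15 nuclei, Cartpt in 108 and Calb2 in 119, and Nos1 in 277 (94.2%, 90.9 to 96.6). Pdyn and Penk, both opioid peptide precursors, were found together in 22 nuclei against a product of 7.17, so that 51.2% (35.5 to 66.7) of Pdyn nuclei had Penk reads, against 16.7% of all nuclei. Grp and Cartpt were found together in 20 nuclei against 11.4, and Cartpt and Calb2 in 58 against 43.7. Cck, Pdyn and Grp seldom coincided, with 2 nuclei for Cck and Pdyn (product 3.95), 1 for Cck and Grp (2.85) and 2 for Pdyn and Grp (4.53), counts too small to set apart from the products. Vip and Calb2 were found together in 4 nuclei against 10.9, and Pdyn and Cartpt in 9 against 15.8, so that 20.9% (10.0 to 36.0) of Pdyn nuclei had Cartpt reads, against 36.7% of all nuclei.

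**Figure D5:**
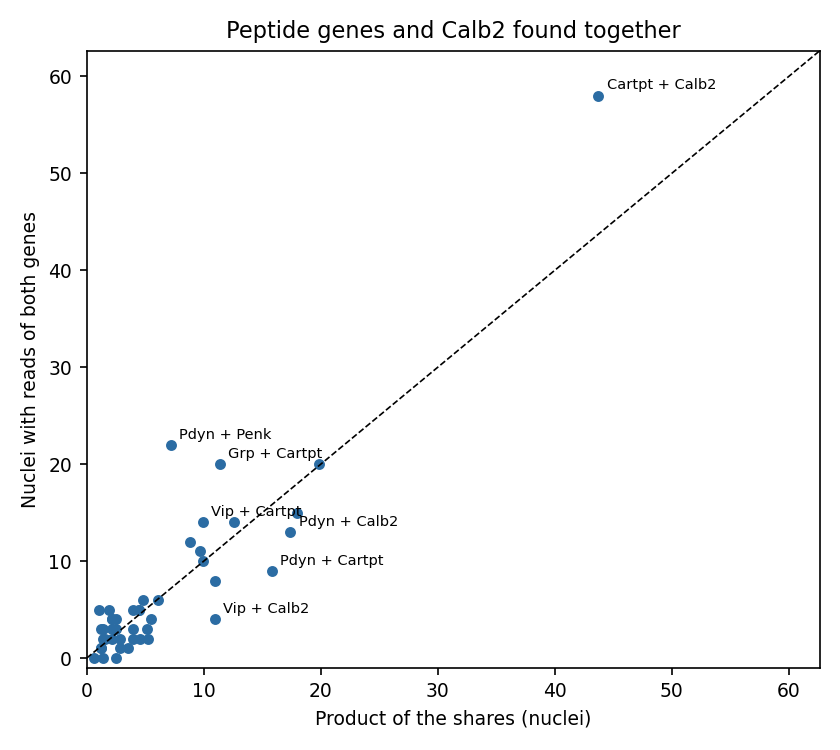
Each point is a pair of peptide genes, or of a peptide gene and Calb2, with the number of nuclei given by the product of the shares on the x axis and the number with reads of both on the y axis, out of 294; the dashed line marks equality. Pdyn with Penk (22 against 7.17) and Grp with Cartpt (20 against 11.4) lie above the line, and Vip with Calb2 (4 against 10.9) below it.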

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

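The tests of cell type markers and immediate early genes were chosen only after the clusters had been seen, as was the test of Hox genes by position; the others were set out before their results were seen. After first values were seen, the rules for the medians of cell type markers, ribosomal protein genes and transcription factors were made stricter, so that the range over resampled genes had to clear the limit, and the rule for ribosomal protein genes within blocks was replaced by one on resampled nuclei, extended to cluster 7. This turned the cell type markers in cluster 1 from supported to open, and the transcription factors in cluster 6 from excluded to open.

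Nuclei left out for few detected genes were not used in any comparison, yet they held reads of neuronal genes above the floor of 3 nuclei (4.48% of 67). Meg3, a long noncoding RNA abundant in neurons, was detected in 58.2% of them, Snap25 in 22.4%, Slc5a7 in 14.9%, and Chat and Slc18a3 in 7.46% each.

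In cluster 1, Atf3 was detected in 66.7% of nuclei against 12.7% of the others. The block of nucleus numbers does not account for this, because the difference was at least 23.8 points within each of the 4 blocks, although 1 block held only 3 nuclei of the cluster. Markers of glial, vascular, ependymal, inhibitory and serotonergic cells were also higher in 45 of 50 cases, with a median of 10.6 points (7.12 to 16.8 when genes were resampled) at the 95.5th percentile of matched lists (median 7.37), while 0 of 6 cholinergic markers were higher. This median is not set apart from the limit of 10 points, so admixture of RNA from other cells, which the mCherry gate should reduce, stays open. Of the axon injury genes other than Atf3, 6 of 10 were higher, and their median lay at the 67.6th percentile of 10000 matched lists, so an injury response may contribute but was not set apart.

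Clusters 2 and 7 had the highest median shares of mitochondrial reads, 0.165% and 0.159%. Ribosomal protein genes, which took no part in the clustering, were higher in each of them than in the single cluster it was compared with. The median log2 ratio was 0.77 (0.69 to 0.84) for cluster 2 over cluster 5 and 0.80 for cluster 7 over cluster 4. Ratios over the remaining clusters were not computed. The smaller ratio, 0.767, is in line with more cytoplasmic RNA carried along with these nuclei. Within each of the 4 blocks both ratios were at least 0.401, and the ranges over resampled nuclei stayed at 0.24 or above, over the 0.2 that an effect of blocks would need, which argues against it, although the stricter limit of 0.5 set beforehand was missed in 1 block. The immediate early list lay at the 100th percentile of 10000 matched lists (median 9.65 points). Those lists were matched on share and not on transcript length, so this rank cannot tell neuronal activity from more cytoplasmic RNA. Activity remains a candidate explanation too.

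Cluster 6 had fewer nuclei with Hoxb5 and Hoxa5. In each of the 3 blocks with at least 3 of its nuclei, the Hoxb5 share was lower by 35 points or more (differences from -78.8 to -35), which argues against the block of nucleus numbers. Of the other 73 listed transcription factors, 56 were lower and 15 higher in cluster 6. Their median difference was -4.91 points (-7.09 to -3.5), which neither excludes nor accounts for a lower detection of factors in general. The 7 Hox genes of groups 4 and 5 found in at least 10% of nuclei were lower, with a median of -31.3 points (-32.9 to -13.6 for those other than Hoxb5 and Hoxa5, which prompted the test), and rarer genes of groups 6 to 8 were left out. A more rostral position of these nuclei may explain this, but the 5 genes of groups 2 and 3 went both ways (median -10.3, from -22.7 for Hoxa3 to 32.6 for Hoxd3, which shares exons with Hoxd4), and the labels give no position. Low shares of groups 4 and 5 were not all particular to cluster 6. Cluster 9, pooled here with the others, had Hoxa4 and Hoxa5 in 0 of 14 nuclei, Hoxb4 in 14.3% and Hoxd4 in 7.14%. In cluster 6 these were 5.26%, 0%, 21.1% and 15.8%. Hoxb5, Hoxc4 and Hoxc5 were higher in cluster 9 (50%, 71.4% and 14.3%) than in cluster 6 (10.5%, 63.2% and 5.26%).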

How the results depend on the processing

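The first clustering without listed genes, the run without cluster 1 and the 20 further seeds were chosen after seeing the data. No paired analysis was possible because there is 1 group. Of the main counts and shares, 114 results under alternatives stayed within their interval or within 1.5 times of the reported value, and 19 moved. Nuclei retained (313 to 329), the visceral motor class (290 to 307) and the number of clusters (6 to 12) were among the former, but the clusters themselves had an adjusted Rand index with the reported ones of only 0.294 (thinned before clustering), 0.379 (at least 2000 genes) and 0.413 (at least 500 genes) up to 0.773 (another seed). The causes of the changes below were not tested.

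With at least 500 genes, Chat was detected in 93.0% of retained nuclei, 69 listed genes passed, the matched clusters held Cck in 14.3% and Pdyn in 16.1% (highest of any cluster 26.7% and 23.7%), and Htr4 reversed (48.8%). With at least 2000 genes Pdyn stood at 60.5%. At resolution 0.5 Cck stood at 35.9%, and with 20 neighbours at 32.6% with 80 genes passing. In the matched cluster Pdyn stood at 15.6% with 10 (highest of any 26.9%) and 55.9% with 20 components, 54.2% with genes in at least 10 nuclei, 52.6% with listed genes kept in and 8.70% with pooled size factors (highest of any 56%). Clusters from thinned reads reversed Oprm1 (90%) and Jund (61.9%). With 5 reads required, 1 nucleus had Cck and Pdyn, and 19 genes were higher in the somatic motor-like class. Within blocks, Pdyn stood at 50% in block 1 and 0% in block 2, and Grp at 0% in blocks 2 and 3. Depth limits detection: 21 visceral motor-like nuclei fell short of 500000 reads.

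Over single genes, 3 results reversed, 240 moved and 2522 did not. Left out of these totals are genes whose highest and lowest cluster were matched to the same cluster under an alternative, so that no difference remained. This held for 6 genes when nuclei with at least 500 genes were kept, 5 at resolution 0.5 and 4 with 20 neighbours. It also held for 1 gene each with at least 2000 genes, 10 components and 20 components. Over 20 seeds, 9 to 10 clusters were found and the highest Cck share stayed at 73.7%.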

Other observations

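The values given here were chosen after seeing the data. Cck was not limited to the visceral motor-like class. It was detected in 9 of 22 somatic motor-like nuclei at 500000 reads (40.9%, 20.7 to 63.6), against 6.96% (4.24 to 10.7) of visceral motor-like nuclei, with 19.2 and 7.19 RPM. The transcription factor genes Isl2, Irx3 and Bcl11a were detected in 40.9%, 36.4% and 50.0% of somatic motor-like nuclei, against 2.20%, 2.93% and 15.4%. Isl2 was among the markers that named the classes and is no independent evidence. Chrm2 was detected in 22 of 22 against 64.1%, with 442.1 and 79.5 RPM, and Th, the rate-limiting enzyme of catecholamine synthesis, in 9.09% against 43.2%.

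The Cck cluster also had Dbh, the enzyme that makes noradrenaline from dopamine, in 63.2% (38.4 to 83.7) of nuclei against 17.7% (13.2 to 23.0). Cartpt was detected there in 5.26% against 38.6%, and Oxtr, the oxytocin receptor gene, in 0 of 19 against 33.1%. Nppb, which encodes a natriuretic peptide, was detected in 54.5% (36.4 to 71.9) of cluster 4, 50.0% (27.2 to 72.8) of cluster 7 and 42.9% (17.7 to 71.1) of cluster 9, and in at most 20.0% of any other cluster. Tac1 and Sst were found together in 5 visceral motor-like nuclei, against a product of 1.06.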
